A study of Mus musculus with 66 samples.

How the data were processed

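RNA sequencing was done on 4 mouse RNA samples: the BC57 bladder cancer cell line and normal urothelium, each kept fresh frozen (FF) or as formalin-fixed, paraffin-embedded material (FFPE). Per the labels' protocols, a BC57 cell pellet and the urothelium of 9 mice were divided into a frozen part and a part held in buffered formalin for 24 hours. How the 9 mice were combined into 1 RNA sample per preservation is not stated in the sources used here. The 66 libraries fall into 22 groups of 3 repeat libraries, by sample, kit and RNA input. Ovation SoLo libraries were made from 50 pg, 250 pg and 2 ng of total RNA, SMARTer Pico libraries from 250 pg and 2 ng, and poly(A) libraries from 1 µg of the FF samples. Both low-input kits are strand specific and start from random priming or template switching on total RNA with depletion of ribosomal sequences, per the labels' protocols. The protocols describe paired-end reads of 100 nucleotides.

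The deposited count tables hold raw read counts per gene for each library. Reads were aligned to mm10 with STAR, handled with SAMtools and counted per gene with featureCounts, per the submitters' processing notes, which give no versions. The gene annotation and the use of strand in counting are not given in the sources used here. The deposited normalized tables hold log2 values, which the authors derived from the same counts. Recomputing log2(count × 1000 / upper quartile of the nonzero counts + 1) gave the deposited log2 values to within 5.33e-14 in all 66 libraries. Counts were the main measure, and the log2 values served as an alternative.

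The tables hold 39179 genes by Ensembl identifier. Symbols, coordinates and biotypes were taken from GENCODE M21 on mm10 (GRCm38), which matched 37693 genes. The other 1486 genes took at most 2.471% of any library and stayed in every test under their identifier. Total counts ran from 928722 to 4706030 in the 36 Ovation libraries (median 3161096.5), from 651879 to 7152648 in the 24 SMARTer libraries (median 4504067) and from 18499591 to 36187226 in the 6 poly(A) libraries (median 28130236).

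For each of 35 comparisons, genes with low counts were removed with filterByExpr. Counts were scaled by TMM and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Group levels are CPM (scaled counts, mean ± SD over 3 libraries) scaled within the comparison, so that a group's CPM differs slightly from comparison to comparison. Log2 fold changes are those of the edgeR fit at its default prior count. Their standard error was derived as the size of the fold change over the square root of the F statistic. A prior count of 2 entered only the log2 CPM of the list tests. For a gene with no count in one group, the fold was computed against a floor of 3 counts over the group and is given as "at least". With 1 to 3 counts, the ratio of CPM is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads from PCR are not independent molecules.

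The 27 gene lists, the comparisons, the alternatives and the choice of named genes were fixed before the data were examined. Lists were tested with camera at an inter-gene correlation of 0.01 (limma 3.58.1), again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. List members are counted at the adjusted p over all genes, and also adjusted over the list alone. In the poly(A) comparison, the named genes were the 10 higher and 10 lower genes of largest fold change with a mean of at least 20 CPM in the higher group. They also needed an adjusted p under 0.05, no overlap between the libraries of both groups, and a symbol other than Gm, Rik, AC, BC or -ps names. Up to 4 members of each list with the largest fold change were added. Other comparisons took 5 genes per direction and up to 2 members of each list described, and the low-input comparisons of BC57 with urothelium took the poly(A) genes. Gapdh, Actb and Upk2 were followed everywhere. In the test of whether formalin fixation acts differently on both samples, 4 groups enter and the criterion of separate libraries is undefined, so it was left out. Groups of 3 that do not overlap arise by chance in 10% of genes.

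Genes were counted as detected at 5 or more counts after every library was thinned without replacement to 651879 counts (seed 117). Correlations between repeat libraries used log2(CPM + 1) of genes with a mean of at least 1 CPM over the kit's libraries. Single measures were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Repeat libraries share an RNA sample, so all p-values measure technical spread and not variation between mice or cultures. No label pairs the libraries across groups, and the replicate number entered only as an alternative.

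On simulated data with 200 changed genes, the edgeR step found 88% of 2-fold and 92% of 4-fold changes among 17934 genes of the poly(A) comparison, with 4.26% false calls. The values were 75%, 92% and 2.34% for Ovation FF at 2 ng (13018 genes), and 71%, 94% and 4.62% for SMARTer FF at 2 ng (14503 genes). For FFPE against FF urothelium with Ovation they were 71%, 92% and 8.43% (13354 genes). For Ovation FFPE at 50 pg (13584 genes), 0% of 2-fold and 9% of 4-fold changes were found, with 18.2% false calls. In the data, more than 200 genes were called in each of these comparisons, so these shares do not carry over to them.

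The alternatives were DESeq2 1.42.0, DESeq2's size factors within edgeR, no filter on low counts, thinning to 1 depth, limma on the deposited log2 values, the replicate number as a block, other detection minimums, rank correlations, and leaving out each library in turn. Leaving out the SMARTer FFPE libraries numbered 3 was added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining steps. No library was excluded from the results as reported. The microarray and NanoString parts of the study were not analysed here.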

Results

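Expression was measured by RNA sequencing in mouse BC57 bladder cancer cells and in mouse normal urothelium, the epithelium that lines the bladder. Both samples existed as frozen and as formalin-fixed, paraffin-embedded material, and each of 22 combinations of sample, preservation, kit and input was sequenced in 3 repeat libraries. Total counts ran from 928722 to 4706030 per Ovation library, from 651879 to 7152648 per SMARTer library and from 18499591 to 36187226 per poly(A) library. Poly(A) libraries from 1 µg of frozen RNA served as the study's reference for the low-input kits. BC57 was compared with urothelium under every condition, then FFPE with FF, low with high input, and kit with kit.

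In the poly(A) reference, BC57 cells and urothelium differed in most of the genes tested. BC57 cells expressed Hmga2, a chromatin protein of embryonic and tumour cells, at 312 ± 6.99 CPM against 0.0555 ± 0.0578 CPM in urothelium (mean ± SD, n = 3 libraries each; log2 fold change 12.45, SE 0.12, adjusted p = 6.32e-26). Msln, which encodes the surface glycoprotein mesothelin, stood at 1075 ± 28.2 against 0.227 ± 0.0206 CPM (log2 fold change 12.16). Urothelium expressed Upk3a, a uroplakin of the urothelial plaque, at 1593 ± 105 CPM against 0.0469 ± 0.0578 CPM in BC57 cells, a ratio of 51104 (95% counting interval 17487 to 247813). The acute-phase protease inhibitor gene Serpina3n was at least 6812-fold lower in BC57 cells, in which it had no count. In all, 16370 of 17934 genes differed by the edgeR quasi-likelihood test, 7672 higher and 8698 lower in BC57 cells, and 10274 of them by at least 2-fold. After all libraries were thinned to 651879 counts, 7414 genes passed.

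Other genes high in BC57 cells and without a count in urothelium were Tmem171 (chromosome 13, 98686235 to 98694834; at least 700-fold), Serpinb7 (at least 674-fold), the endodermal and cardiac transcription factor gene Gata4 (chromosome 14, 63198922 to 63271692; at least 669-fold), Wnt7a (at least 645-fold) and Gad2 (at least 620-fold). The claudin genes Cldn3 and Cldn6 were also higher, Cldn3 at a ratio of 5187 (1435 to 42832) and Cldn6 by 12.22 on the log2 scale, as was Dynap, by 11.93. Lower in BC57 cells without a count were Gsdmc3 (at least 4018-fold), the monocarboxylate transporter gene Slc16a7 (at least 3905-fold), Glb1l2 (at least 3455-fold) and Kctd12 (at least 3344-fold). The imprinted long noncoding RNA Meg3 was lower at a ratio of 34094 (6119 to 1346671), Cyp4f15 at 33510 and Gsdmc2 at 22680. Sptssb had a log2 fold change of -14.19.

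Genes of urothelial differentiation were mostly lower in BC57 cells: 13 of the 19 fell, 5 rose and 1 did not pass, by the adjustment over all genes and adjusted over the list alone. Upk1a changed by -10.52, Upk2 by -8.27 (3.13 ± 0.107 against 968 ± 44.2 CPM) and Upk3b by -6.76 on the log2 scale. The list median was -3.46 (camera adjusted p = 0.0322), with adjusted p = 0.470 with an estimated correlation. The 17 basal and squamous keratinocyte genes went both ways, 11 higher and 6 lower (adjusted p = 0.230). The basal keratin Krt15 and the transcription factor Trp63 were lower, by -9.41 and -8.98, while the stress keratin Krt6a was higher, by 8.04. Of 15 epithelial junction genes, 7 were higher, among them Epcam (2.33), and 6 lower, among them the splicing regulator Esrp2 (-2.22), with adjusted p = 0.582. Of 16 genes of mesenchymal transition, 11 were lower, among them Mmp2 (-8.49) and Sparc (-5.81), and 5 higher (median -0.54, adjusted p = 0.230). Twist1 had no count in BC57 cells and was at least 64.9-fold lower.

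All 30 cell cycle genes were higher in BC57 cells, over all genes and adjusted over the list alone, with a median of 5.30 on the log2 scale (camera adjusted p = 3.37e-11). This call held with an estimated correlation (adjusted p = 0.0334). The cyclin gene Ccnb1 stood at 235 ± 4.26 against 2.09 ± 0.0844 CPM (6.81, SE 0.064), and Ube2c, Birc5 and Cdk1 rose by 6.78, 6.68 and 6.63. Glycolysis genes rose in 12 of 15 cases, with 2 lower and a median of 1.35 (adjusted p = 2.51e-03; adjusted p = 0.459 with an estimated correlation), led by Pgk1 (4.26), Eno1 (3.20) and Ldha (2.85). Cholesterol synthesis genes rose in 17 of 18 cases with a median of 0.76, among them Cyp51 (1.65) and Insig1 (1.49). Their adjusted p was 5.13e-04, and adjusted p = 0.238 with an estimated correlation. Of 74 nuclear genes of oxidative phosphorylation, 60 were higher and 13 lower, with a median of 0.54 (adjusted p = 1.34e-04; adjusted p = 0.470 with an estimated correlation), among them Atp5g1 (1.76) and Uqcrq (1.69). All 13 housekeeping genes were higher, with a median of 0.88 (adjusted p = 2.84e-04; adjusted p = 0.161 with an estimated correlation), Actb by 2.12 and Gapdh by 2.79. Immediate early and heat shock genes were higher in 11 of 14 cases and lower in 2 (median 1.03, adjusted p = 0.0137; adjusted p = 0.470 with an estimated correlation), with Atf3 at 5.53, Egr1 at 4.21 and Hspa1a at -4.49.

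Markers of the other cell types of the bladder wall were lower in BC57 cells. All 12 fibroblast genes fell (median -9.48, adjusted p = 1.34e-04; adjusted p = 0.238 with an estimated correlation), and the collagen gene Col1a1 stood at 0.587 ± 0.199 against 2412 ± 203 CPM (-11.91). All 10 smooth muscle genes fell (median -4.93, adjusted p = 1.68e-03; adjusted p = 0.258 with an estimated correlation), among them Myh11 (-7.80) and Acta2 (-5.93). All 10 endothelial genes fell (median -8.79, adjusted p = 1.68e-03; adjusted p = 0.180 with an estimated correlation), among them the receptor gene Kdr (-9.13). Of 13 immune genes, 12 fell and 1 rose (median -8.91, adjusted p = 1.68e-03; adjusted p = 0.403 with an estimated correlation), among them H2-Eb1 (-9.83) and Lyz2 (-9.80). All 5 erythroid genes tested fell (median -3.77, adjusted p = 0.0309; adjusted p = 0.432 with an estimated correlation), with the globin gene Hbb-bs at least 770-fold lower, although reads of Hbb-bs and Hbb-bt are hard to tell apart. The frozen urothelium held transcripts of fibroblast, muscle, endothelial and blood marker genes, which BC57 cells held at lower levels. The only adipocyte gene tested, Fabp4, changed by -6.65. Of 8 Schwann and neural genes, 5 were lower and 2 higher (median -2.69, adjusted p = 0.315), and of 4 skeletal muscle genes, 2 were lower and 2 higher (median -0.29, adjusted p = 0.919).

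The 13 mitochondrially encoded protein genes were lower in BC57 cells, 12 over all genes and 13 adjusted over the list alone, among them mt-Nd4 (-2.28) and mt-Co1 (-2.26). Their median was -1.77 (adjusted p = 0.0140; adjusted p = 0.470 with an estimated correlation). The remaining lists did not pass camera. The counts were 4 higher and 8 lower of 12 p53 target genes (adjusted p = 0.367), 5 higher and 9 lower of 15 interferon genes (adjusted p = 0.700), and 5 higher and 3 lower of 9 MHC class I genes (adjusted p = 0.472). Examples were Eda2r at -5.47, Bst2 at 2.61 and Psmb8 at 1.42. Both mitochondrial rRNA genes were higher (median 0.58, adjusted p = 0.385), as were 5 of 10 small noncoding RNA genes with 2 lower (median 0.62, adjusted p = 0.385), while 7 of 10 nuclear long noncoding RNA genes were lower and 3 higher (median -1.66, adjusted p = 0.244). Of 20 replication-dependent histone genes, 12 were lower and 5 higher (median -1.16, adjusted p = 0.398), and reads can be shared among histone paralogs. Cytosolic ribosomal protein genes went both ways, 35 higher and 27 lower of 83. Their median of 0.03 and the test pointed up and their mean of -0.06 down (adjusted p = 0.385).

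The low-input kits asked how much of this difference can be seen from picograms and nanograms of RNA, and from fixed material. At 2 ng of frozen RNA both kits gave fold changes near those of poly(A) for the 3 genes followed throughout. Upk2 changed by -8.11 with Ovation and by -7.96 with SMARTer, Gapdh by 2.78 and 2.68, and Actb by 2.09 and 2.16 on the log2 scale (poly(A): -8.27, 2.79 and 2.12; n = 3 libraries per group). All 30 cell cycle genes were higher (medians 4.82 and 5.0; adjusted p = 8.99e-13 and 4.85e-13), and these calls held with an estimated correlation (adjusted p = 0.0252 and 0.0251). All 11 fibroblast genes tested with Ovation and all 12 with SMARTer were lower, with medians of -9.54 and -8.73, or -8.05 and -7.43 with genes without a count at their bound (adjusted p = 1.19e-05 and 4.06e-06; adjusted p = 0.0633 and 0.123 with an estimated correlation). Histone genes, whose replication-dependent transcripts lack a poly(A) tail, were higher in BC57 cells in 49 of 52 genes with Ovation and 51 of 53 with SMARTer, with medians of 4.05 and 4.34 where the poly(A) median was -1.16. Their adjusted p values were 2.37e-14 and 4.77e-14, and adjusted p = 0.151 and 0.110 with an estimated correlation.

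At 2 ng, 10291 of 13018 genes differed between BC57 cells and urothelium with Ovation on FF (4896 higher, 5395 lower) and 11183 of 14530 on FFPE (5326 and 5857). With SMARTer, 11244 of 14503 genes differed on FF (5267 and 5977) and 4489 of 14974 on FFPE (2052 and 2437). At 250 pg the counts were 6306 (Ovation FF), 7374 (Ovation FFPE), 7235 (SMARTer FF) and 1244 (SMARTer FFPE), and at 50 pg 5851 (Ovation FF) and 4554 (Ovation FFPE). The Ovation FF count at 250 pg includes urothelium library 3. At equal depth that library detected 10129 genes, against 11159 and 11109 in libraries 1 and 2. After thinning, 6709 genes passed with Ovation on FFPE and 5985 with SMARTer on FF at 2 ng. Both SMARTer FFPE counts rested on single libraries. At 2 ng the count was 1121 without BC57 library 1, 1176 without BC57 library 2, 1504 and 1416 without urothelium library 1 or 2, and 7408 without urothelium library 3. At 250 pg it was 161, 172 and 626 without BC57 library 1, 2 or 3, 179 and 197 without urothelium library 1 or 2, and 2628 without urothelium library 3. Without both libraries numbered 3 the counts were 9280 at 2 ng and 2963 at 250 pg, and DESeq2 called 5708 and 2549.

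The share of the 16370 poly(A) calls that were called in the same direction rose with input. Calls that the low-count filter left untested at low input count as not recovered. At 2 ng on FF with Ovation, 11946 of the 16370 were tested and 9861 recovered. For SMARTer, 13192 were tested and 10848 recovered. The share of all 16370 with Ovation was 34.7% at 50 pg, 37.5% at 250 pg and 60.2% at 2 ng on FF. On FFPE it was 26.4%, 42.5% and 62.7%. The Ovation FF share at 250 pg includes urothelium library 3, named above. SMARTer recovered 43.3% at 250 pg and 66.3% at 2 ng on FF, and 7.32% and 26.5% on FFPE, or 17.3% and 53.4% without both libraries numbered 3. Single left-out libraries moved these SMARTer FFPE shares to between 6.60% (without BC57 library 1) and 43.5% (without urothelium library 3) at 2 ng, and between 0.941% and 15.5% (the same libraries) at 250 pg. After thinning of the low-input libraries alone, recovery at 2 ng was 40.2% and 38.4% with Ovation on FF and FFPE, and 35.2% and 21.9% with SMARTer. With the poly(A) libraries thinned too, the share of their fewer calls was 58.3%, 59.5% and 44.9% for Ovation FF at 50 pg and 250 pg and FFPE at 50 pg, and 17% and 44.2% for SMARTer FFPE at 250 pg and 2 ng. Between 98% and 99.6% of the genes called in both went the same way. For Ovation FF at 50 pg, 5687 genes were shared in direction (2650 for independent lists), and for SMARTer FF at 2 ng, 10848 (5125). The 118 genes were named from poly(A) mostly for large fold change. At 2 ng on FF, 93 of 99 tested were recovered with Ovation (5 opposite) and 102 of 110 with SMARTer (6). At 50 pg Ovation gave 87 of 96 on FF (4) and 79 of 100 on FFPE (2). SMARTer FFPE gave 75 of 106 at 2 ng (1) and 44 of 97 at 250 pg (0).

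**Figure D1:**
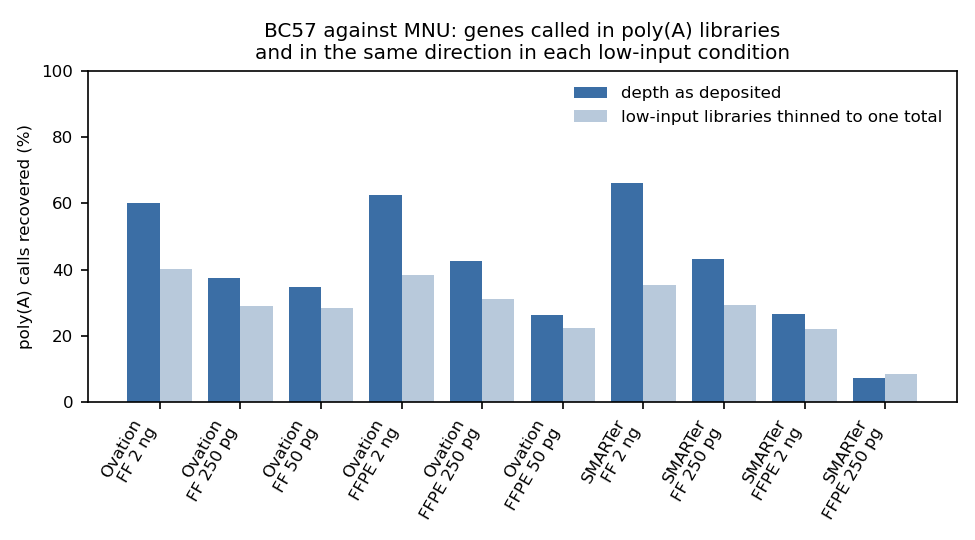
Recovery of the poly(A) calls between BC57 cells and urothelium, in percent of the 16370 genes, by kit, preservation and RNA input. Recovery was 66.3% for SMARTer FF at 2 ng and 7.32% for SMARTer FFPE at 250 pg.

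Upk2 stayed far lower in BC57 cells under all 10 low-input conditions, from -8.51 (Ovation FFPE at 50 pg) to -4.97 (SMARTer FFPE at 250 pg, adjusted p = 0.0134). The last call was lost without BC57 library 1 or 2 (adjusted p = 0.0902 and 0.104) and without urothelium library 1 or 2 (adjusted p = 0.0843 and 0.075). Gapdh was higher in BC57 cells by 2.68 to 2.78 with both kits on FF, and by 3.19 to 3.57 on FFPE. Actb was higher by 2.58 with SMARTer FFPE at 250 pg (adjusted p = 0.0306) and by 2.90 at 2 ng (adjusted p = 0.0221). Neither Actb call held without some single libraries: at 250 pg BC57 library 1, 2 or 3 or urothelium library 1 or 2 (adjusted p from 0.0972 to 0.177), and at 2 ng BC57 library 1 or 2 or urothelium library 1 or 2 (adjusted p from 0.108 to 0.145). Across genes, which are not independent replicates, the fold changes correlated with those of poly(A) at r = 0.927, 0.951 and 0.970 for Ovation FF at 50 pg, 250 pg and 2 ng, and at 0.897, 0.926 and 0.952 for Ovation FFPE. SMARTer gave 0.939 and 0.959 on FF at 250 pg and 2 ng, and 0.780 and 0.859 on FFPE. Spearman's rho was 0.973 for Ovation and 0.974 for SMARTer on FF at 2 ng.

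FFPE and FF libraries differed in several RNA classes in both samples. With Ovation at 2 ng, Neat1, a long noncoding RNA of nuclear paraspeckles, stood at 2849 ± 124 CPM in FFPE and 190 ± 11.6 CPM in FF BC57 cells (n = 3 each; log2 fold change 3.91, SE 0.064), and at 1736 ± 28.4 and 528 ± 4.62 CPM in urothelium (1.72). The vault RNA Vaultrc5 rose by 5.42 and the minor spliceosome RNA Rnu12 by 4.90 in BC57 cells, and Rnu12 by 6.35 in urothelium. Among the named genes, histone genes had the largest decreases, Hist1h2ad by -2.02 in BC57 cells and Hist1h4m by -3.77 in urothelium. Gapdh changed by -0.54 in BC57 cells and by -1.28 in urothelium, Actb by -0.30 and -0.66, and Upk2 by -0.09 in urothelium (adjusted p = 0.319).

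In BC57 cells with Ovation, 3916 of 12127 genes differed (2019 higher, 1897 lower in FFPE), 851 of them by at least 2-fold, and 1727 after thinning. Of 19 small noncoding RNA genes, 18 rose (median 2.32, adjusted p = 6.49e-16; adjusted p = 0.0693 with an estimated correlation). Mitochondrially encoded protein genes rose in 12 of 13 cases (median 1.54, adjusted p = 5.18e-12; adjusted p = 0.283 with an estimated correlation), among them mt-Nd4l (2.49) and mt-Co2 (2.38), and both mitochondrial rRNA genes rose by 1.96 (adjusted p = 1.90e-03; adjusted p = 0.304 with an estimated correlation). All 8 nuclear long noncoding RNA genes rose (median 1.52, adjusted p = 9.22e-09; adjusted p = 0.144 with an estimated correlation). Airn, which overlaps the gene Igf2r on the other strand, had a ratio of 22.9 (7.66 to 113). Of 56 histone genes, 28 fell and 6 rose, or 7 rose adjusted over the list alone (median -0.35, adjusted p = 3.38e-04; adjusted p = 0.567 with an estimated correlation). Cell cycle genes fell in 16 of 30 cases, and 17 adjusted over the list alone, with 1 higher (median -0.27, adjusted p = 1.74e-04; adjusted p = 0.104 with an estimated correlation), led by the replication genes Mcm6 (-0.69) and Mcm3 (-0.63). Glycolysis genes fell in 7 of 14 cases and housekeeping genes in 9 of 13 with 1 higher (both adjusted p = 5.65e-03; adjusted p = 0.359 with an estimated correlation), and cholesterol synthesis genes in 5 of 18 (adjusted p = 0.0151; adjusted p = 0.359 with an estimated correlation).

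In urothelium with Ovation, 4975 of 13354 genes differed (2582 higher, 2393 lower in FFPE), 1274 of them by at least 2-fold, and 2368 after thinning. Of 17 urothelial differentiation genes 13 fell (median -0.55, adjusted p = 5.52e-06; adjusted p = 0.112 with an estimated correlation), led by the keratin genes Krt18 (267 ± 31.7 against 994 ± 73.1 CPM, -1.89) and Krt8 (-1.81). Of 11 keratinocyte genes 9 fell and 1 rose (median -0.83, adjusted p = 8.50e-05; adjusted p = 0.137 with an estimated correlation), among them Krt15 (-1.38), and of 14 junction genes 8 fell (median -0.41, adjusted p = 4.37e-05; adjusted p = 0.112 with an estimated correlation), among them Epcam (-1.25). Of 15 mesenchymal transition genes 8 rose (median 0.52, adjusted p = 0.0103; adjusted p = 0.112 with an estimated correlation), among them Snai1 (1.60) and Zeb1 (1.08), and of 11 fibroblast genes 7 rose and 2 fell (median 0.52, adjusted p = 0.0375; adjusted p = 0.444 with an estimated correlation), among them Col6a3 (0.96), with Pi16 at -0.75. The smooth muscle, endothelial and immune lists did not pass, with medians of 0.21, -0.15 and -0.00 (adjusted p = 0.125, 0.580 and 0.948). FFPE and FF urothelium thus differed in epithelial and fibroblast markers in the same libraries that gave the other FFPE differences. With the replicate number as a block, the fibroblast list no longer passed camera (adjusted p = 0.0636).

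Histone genes fell in 25 of 30 cases in urothelium (median -1.47, adjusted p = 1.46e-10; adjusted p = 0.112 with an estimated correlation), and small noncoding RNA genes rose in 15 of 18 with 1 lower (median 2.30, adjusted p = 7.68e-10; adjusted p = 0.112 with an estimated correlation). Rnu5g, a spliceosomal RNA, rose at a ratio of 132 (44.8 to 641) and Snord118 at 99.3 (27.2 to 824). Cholesterol synthesis genes fell in 14 of 18 cases (median -0.58, adjusted p = 1.20e-05; adjusted p = 0.112 with an estimated correlation), and nuclear oxidative phosphorylation genes in 32 of 71 with 4 higher, or 34 and 5 adjusted over the list alone (median -0.36, adjusted p = 1.70e-05; adjusted p = 0.112 with an estimated correlation). Ribosomal protein genes fell in 46 of 82 cases and rose in 13, or 47 and 14 adjusted over the list alone (median -0.23, adjusted p = 1.30e-03; adjusted p = 0.535 with an estimated correlation). Housekeeping genes fell in 8 of 13 cases with 1 higher, glycolysis genes in 9 of 15 and cell cycle genes in 6 of 16 (adjusted p = 3.04e-04, 5.39e-03 and 0.0439; adjusted p = 0.112, 0.253 and 0.196 with an estimated correlation). Mitochondrially encoded protein genes rose in 11 of 13 cases, nuclear long noncoding RNA genes in 7 of 9, and both mitochondrial rRNA genes rose (medians 0.42, 0.54 and 0.59). Their adjusted p values were 1.79e-04, 1.02e-03 and 0.0430, and adjusted p = 0.253, 0.112 and 0.306 with an estimated correlation. The mitochondrial rRNA list did not pass camera with the replicate number as a block (adjusted p = 0.0705).

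**Figure D2:**
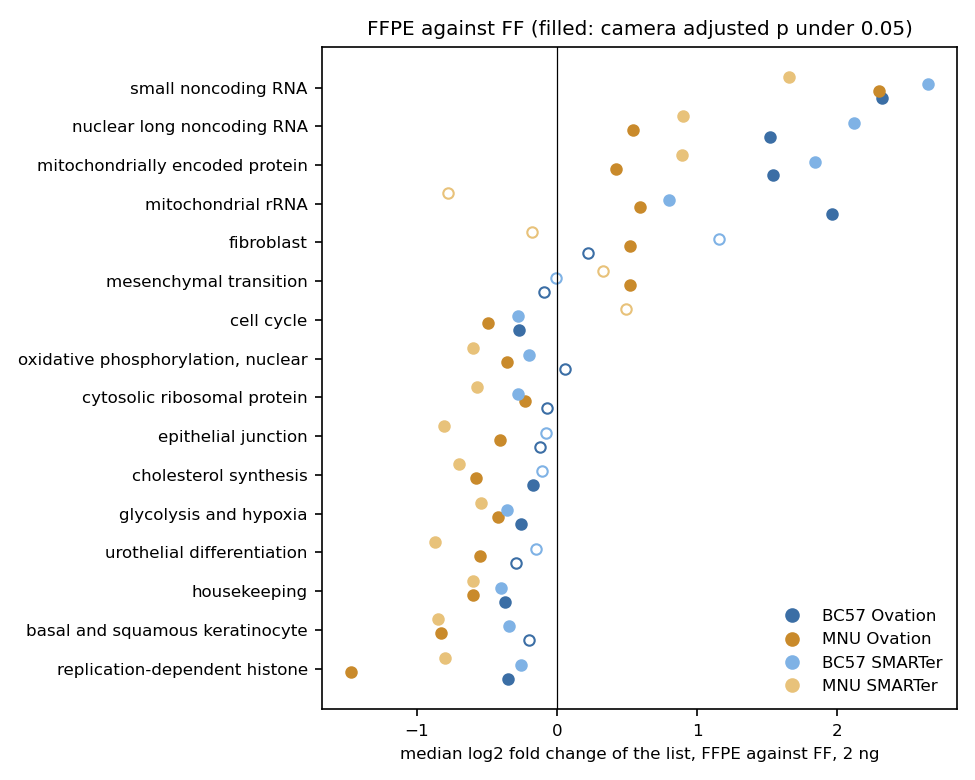
Median log2 fold change of FFPE over FF at 2 ng per gene list, for BC57 cells and urothelium with each kit. The small noncoding RNA medians were 2.32 and 2.30 with Ovation, and the histone medians -0.35 and -1.47.

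With SMARTer at 2 ng the same RNA classes rose in FFPE BC57 cells. Neat1 stood at 1654 ± 136 against 128 ± 15.8 CPM (3.70), Vaultrc5 rose by 6.53 and the mitochondrial gene mt-Nd6 by 2.63. All 13 mitochondrially encoded protein genes (median 1.84, adjusted p = 1.50e-14; adjusted p = 0.241 with an estimated correlation), all 18 small noncoding RNA genes (median 2.65, adjusted p = 8.27e-14; adjusted p = 0.281 with an estimated correlation) and all 8 nuclear long noncoding RNA genes (median 2.12, adjusted p = 1.64e-08; adjusted p = 0.0816 with an estimated correlation) were higher. Both mitochondrial rRNA genes rose (median 0.80, adjusted p = 0.0362; adjusted p = 0.395 with an estimated correlation). Ribosomal protein genes fell in 31 of 82 cases, or 44 with 2 higher adjusted over the list alone (median -0.28, adjusted p = 5.91e-09; adjusted p = 0.395 with an estimated correlation), led by Rpl19 (-0.86). Cell cycle genes fell in 10 of 30 cases with 1 higher, oxidative phosphorylation genes in 16 of 71 and histone genes in 15 of 54 with 1 higher (adjusted p = 2.01e-04, 3.70e-04 and 5.28e-04, each with adjusted p = 0.395 with an estimated correlation). Glycolysis genes fell in 7 of 14 cases and housekeeping genes in 6 of 13 (adjusted p = 3.89e-03 and 5.66e-03; adjusted p = 0.241 and 0.395 with an estimated correlation). Keratinocyte genes fell in 5 of 15 cases with 1 higher (adjusted p = 0.0324; adjusted p = 0.281 with an estimated correlation, and 0.0809 without FFPE library 3). In all 2291 of 12859 genes differed, 1189 higher and 1102 lower, and 1203 or 1164 without FF library 1 or 2, or 837 after thinning. Gapdh changed by -0.57 and Actb by -0.40 (adjusted p = 0.0154). The Actb call was lost without FF library 1 or 2 (adjusted p = 0.0895 and 0.0716) and after thinning (-0.29, adjusted p = 0.121).

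In urothelium with SMARTer, 271 of 14512 genes differed between FFPE and FF, 191 higher and 80 lower, and the count depended on every library. It was 0 without FF library 1 or 2, 4 without FF library 3, 4 and 3 without FFPE library 1 or 2, and 4124 without FFPE library 3. DESeq2 called 1835 genes, edgeR without a filter 85 and edgeR with the replicate number as a block 76, and 3536 genes had an unadjusted p under 0.05. Snora81, a small nucleolar RNA, stood at 103 ± 66.4 CPM in FFPE and 2.70 ± 0.121 CPM in FF (5.19, adjusted p = 0.0120), and the linker histone gene Hist1h1c at 18.2 ± 3.33 and 68.6 ± 5.45 CPM (-1.95, adjusted p = 0.0176). The Snora81 call was lost without FF library 1, 2 or 3 (adjusted p = 0.267, 0.189 and 0.149), and the Hist1h1c call without any library but FFPE library 3 (adjusted p from 0.0943 to 0.267). Small noncoding RNA genes rose in 8 of 17 cases, and 12 adjusted over the list alone (median 1.66, adjusted p = 1.95e-09; adjusted p = 0.322 with an estimated correlation). In 10 lists camera passed while at most 2 members did: oxidative phosphorylation, ribosomal protein, urothelial, junction, histone, keratinocyte, cholesterol, housekeeping and glycolysis genes were placed lower than other genes, and mitochondrially encoded protein genes higher. Their camera adjusted p ran from 8.18e-10 to 3.10e-03, and adjusted p = 0.322 was the lowest with an estimated correlation. Nuclear long noncoding RNA genes rose in 1 of 10 cases (median 0.90, adjusted p = 6.90e-03; adjusted p = 0.407 with an estimated correlation).

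The FFPE differences were shared between samples and kits. Across genes, the Ovation log2 fold changes of BC57 cells and urothelium correlated at r = 0.710 (rho = 0.636, 10905 genes). Of 2250 genes called in both, 2199 went the same way, where independent lists would share 669. In BC57 cells, Ovation and SMARTer correlated at r = 0.779, and 1560 of 1577 genes called in both went the same way (345 for independent lists). In urothelium they correlated at r = 0.695, with 236 of 236 (46.7 for independent lists), or 2589 of 2624 without SMARTer FFPE library 3.

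Whether FFPE effects differed between the samples was tested at 2 ng. With Ovation, 857 of 14527 genes differed, 619 with a higher FFPE effect in BC57 cells and 238 with a lower one, and 272 after thinning. The histone gene Hist1h4m stood at 11.7 ± 1.04 in FFPE and 7.10 ± 1.80 CPM in FF BC57 cells but at 2.26 ± 0.974 and 32.1 ± 2.89 CPM in urothelium (n = 3 each; log2 difference 4.49, SE 0.43, adjusted p = 3.92e-12). Nexn, an actin-binding protein gene of muscle, had a difference of -1.99 (adjusted p = 3.08e-07), with 39 ± 4.74 against 12.6 ± 0.655 CPM in urothelium. Rnu5g stood at 28 ± 5.37 in FFPE and 3.31 ± 1.05 CPM in FF BC57 cells, and at 66 ± 11.3 and 0.458 ± 0.435 CPM in urothelium (adjusted p = 0.000127; 0.051 after thinning). With SMARTer, edgeR called 0 of 16574 genes, with 1423 at an unadjusted p under 0.05, and DESeq2 called 74. There edgeR called 168 genes without FFPE urothelium library 3 and 306 without a filter, and DESeq2's size factors shifted the median of all genes by -0.17 on the log2 scale.

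Between inputs few genes passed, but the others are not shown to be unchanged. With Ovation, 50 pg against 2 ng of FF BC57 RNA changed 3 of 11259 genes, all named here after their values were seen. These were the mitochondrial genes mt-Nd3 (1798 ± 73.4 against 1247 ± 64.0 CPM, 0.53, adjusted p = 0.0162) and mt-Nd2 (0.37, adjusted p = 0.0162) and the small nuclear RNA gene Gm24265 (1.25, adjusted p = 0.0407). In FFPE urothelium, 3 of 13899 genes changed, mt-Rnr1 (0.56, adjusted p = 0.0380), mt-Rnr2 (0.49, adjusted p = 0.0121) and Gm23935 (-0.56, adjusted p = 0.0121), an annotated microRNA gene. EdgeR called 0 of 12817 genes in FFPE BC57 cells and 0 of 12801 in FF urothelium, with 848 and 706 at an unadjusted p under 0.05. DESeq2 called 35, 23, 171 and 23 genes in these groups in turn. The FF BC57 count was 61 without a filter, 16 after thinning, 0 without 2 ng library 1 or 2 or 50 pg library 2 or 3, and 5 and 15 without 2 ng library 3 and 50 pg library 1. The FFPE urothelium count was 0 without any 2 ng library or 50 pg library 1 or 3, and the Gm23935 call was also lost without 50 pg library 2 (adjusted p = 0.0637). In FF urothelium edgeR called 2 genes without 50 pg library 3. Gapdh, Actb and Upk2 did not pass in any comparison of inputs.

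At 250 pg against 2 ng with Ovation, 23 of 11641 genes changed in FF BC57 cells (22 higher) and 13 of 12780 in FFPE BC57 cells (11 higher). Mitochondrial mt-Rnr1 rose by 0.60 in FF BC57 cells (adjusted p = 0.000221), and mt-Nd2 by 0.36 in FFPE BC57 cells. The FF count was 59 without a filter, 14 after thinning, 8 and 49 without 250 pg library 2 or 3 and 10 and 11 without 2 ng library 1 or 2, and the FFPE count was 8 without 250 pg library 2, 34 without a filter and 29 by DESeq2. In FFPE urothelium, mt-Rnr2 alone passed among 14087 genes (0.20, adjusted p = 0.0395), and that count was 0 without 250 pg library 1 or 2 or 2 ng library 2 or 3, and 3 without 250 pg library 3. In FF urothelium edgeR called 0 of 12929 genes (343 at an unadjusted p under 0.05; DESeq2 0), or 6 without 250 pg library 3. With SMARTer, edgeR called 0 genes in FF and FFPE BC57 cells and in FF and FFPE urothelium, with 492, 427, 588 and 142 at an unadjusted p under 0.05 and 0, 7, 2 and 0 by DESeq2.

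In each sample, kit and preservation, repeat libraries correlated less at 250 pg and 50 pg than at 2 ng. Across genes, the mean r between Ovation libraries of FF BC57 cells was 0.984 at 2 ng, 0.971 at 250 pg and 0.927 at 50 pg, and that of FFPE urothelium 0.972, 0.905 and 0.834. In FF urothelium it was 0.975, 0.881 and 0.886, and at 250 pg 0.846 and 0.85 for the pairs with library 3 and 0.947 without it. The means stood against 0.999 and 0.998 for poly(A) libraries of BC57 cells and urothelium. SMARTer FF libraries gave 0.987 in both samples at 2 ng, and 0.962 and 0.95 at 250 pg. SMARTer FFPE urothelium gave 0.671 at 2 ng, with 0.526 and 0.522 for the pairs with library 3 and 0.966 without it, and 0.482 at 250 pg, with 0.303 and 0.297 for the pairs with library 3 and 0.844 without it.

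At equal depth, the genes detected in Ovation libraries fell from 10221 ± 8.96 at 2 ng to 10053 ± 77.3 at 50 pg in FF BC57 cells (98.4%; n = 3, exact permutation p = 0.1, the smallest possible) and from 11605 ± 35.3 to 11148 ± 104 in FFPE urothelium (96.1%; exact permutation p = 0.1). At a minimum of 1 count instead of 5, the shares were 92.7% and 84.3%. In SMARTer FF libraries, 9613.3 ± 45.1 genes at 250 pg stood against 9662.3 ± 33.5 at 2 ng in BC57 cells, and 10584 ± 6.35 against 10662 ± 85.2 in urothelium. SMARTer FFPE urothelium had 12521 ± 2954 and 14689 ± 5468. Its library 3 at 2 ng had 21003 genes against 11489 and 11576 in libraries 1 and 2, and without it the difference between inputs turned from -2168.3 to 988.5 genes. Library 3 at 250 pg had 15915 genes, and without both libraries numbered 3 the difference was -708.5. In FFPE BC57 cells it turned from -228.7 to 419.2 without 2 ng library 3, where 11912 genes were detected, and to 26.7 or 77.7 without 250 pg library 1 or 2. It was -142.5 without both libraries numbered 3. Poly(A) libraries had 10390 ± 11 genes in BC57 cells and 11566 ± 21.2 in urothelium.

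**Figure D3:**
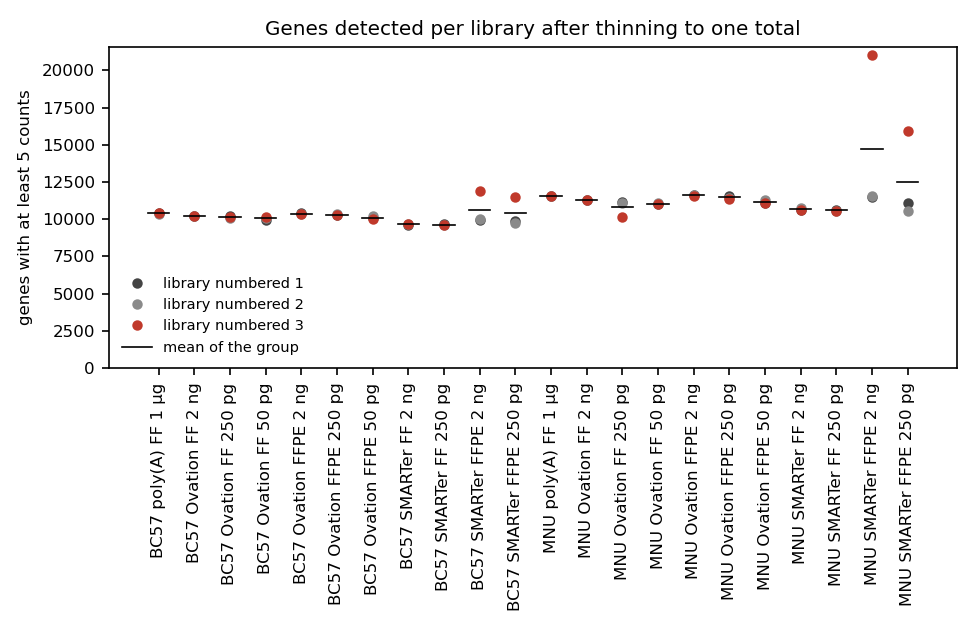
Genes with at least 5 counts per library after thinning to 651879 counts, by sample, kit, preservation and input. SMARTer FFPE urothelium library 3 at 2 ng had 21003 genes, against 11489 and 11576 in the other two.

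The kits differed in the RNA classes they captured from the same FF RNA. Ovation and SMARTer libraries held histone and small noncoding RNAs that poly(A) libraries nearly lacked. In urothelium, the small Cajal body RNA Scarna10 and the Y RNA Rny3 were at least 5960-fold and at least 5989-fold higher with Ovation than with poly(A), and the 7SK RNA gene Rn7sk stood at 25064 ± 2221 against 3.69 ± 0.823 CPM (12.74). In BC57 cells, Hist1h4d stood at 644 ± 97.8 with Ovation and 0.0863 ± 0.0408 CPM with poly(A) (12.65), and at 257 ± 26.2 against 0.0758 ± 0.0358 CPM with SMARTer (11.51). Actb was higher than with poly(A) by 1.76 and 1.63 with Ovation, and by 1.20 and 1.04 with SMARTer, in BC57 cells and urothelium. Gapdh was lower, by -0.78 and -0.92, and by -1.23 and -1.24. Upk2 in urothelium changed by -1.24 with Ovation and by -0.38 with SMARTer.

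Between Ovation and poly(A), 8471 of 14137 genes differed in BC57 cells and 9123 of 16081 in urothelium (3955 and 4207 after thinning). Histone genes were higher in 55 of 56 and 39 of 42 cases (medians 9.66 and 5.95, the first 9.56 with genes without a count at their bound; adjusted p = 8.93e-32 and 1.48e-20; adjusted p = 0.0404 and 0.112 with an estimated correlation). All 17 and all 15 small noncoding RNA genes were higher (medians 8.38 and 11.21, the second 11.03 with bounds; adjusted p = 1.12e-12 and 2.63e-14; adjusted p = 0.0322 and 0.0325 with an estimated correlation), as were all 13 mitochondrially encoded protein genes in both samples (medians 2.42 and 2.04, adjusted p = 3.98e-10 and 2.41e-09; adjusted p = 0.0974 and 0.349 with an estimated correlation). Both mitochondrial rRNA genes were higher too (medians 4.38 and 5.95, adjusted p = 8.84e-03 and 7.09e-03; adjusted p = 0.387 and 0.349 with an estimated correlation). Ribosomal protein genes were lower in 71 of 82 cases with 5 higher, and in 78 of 83 with 2 higher (medians -0.62 and -0.95, adjusted p = 1.18e-13 and 3.90e-20; adjusted p = 0.447 and 0.202 with an estimated correlation), led by Rps18 (-1.93 and -2.34). Nuclear oxidative phosphorylation genes were lower in 52 of 72 and 57 of 74 cases, with 9 and 2 higher (medians -0.45 and -0.66, adjusted p = 1.36e-05 and 3.57e-11; adjusted p = 0.602 and 0.0396 with an estimated correlation). In BC57 cells MHC class I genes were lower in 7 of 9 cases and nuclear long noncoding RNA genes higher in 6 of 8, with Malat1 at 3.70 (both adjusted p = 0.0373; adjusted p = 0.433 and 0.447 with an estimated correlation). In urothelium glycolysis genes were lower in 10 of 15 and urothelial genes in 13 of 18 cases (adjusted p = 4.82e-03 and 7.30e-03; adjusted p = 0.349 and 0.457 with an estimated correlation).

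Between SMARTer and poly(A), 8336 of 14506 genes differed in BC57 cells and 9404 of 16294 in urothelium (3126 and 3498 after thinning). Histone genes were higher in 53 of 54 and 31 of 35 cases (medians 8.44 and 4.71, the first 8.12 with bounds; adjusted p = 2.50e-30 and 3.34e-13; adjusted p = 0.107 and 0.0960 with an estimated correlation), and small noncoding RNA genes in 15 of 16 in both samples (medians 6.07 and 9.30, the second 9.01 with bounds; adjusted p = 2.36e-09 and 1.03e-11; adjusted p = 0.357 and 0.250 with an estimated correlation). The mitochondrial rRNA gene mt-Rnr1 was higher by 6.94 and 8.42. Ribosomal protein genes were lower in 50 of 82 cases with 21 higher, and in 58 of 83 with 15 higher (medians -0.37 and -0.57, adjusted p = 3.86e-03 and 1.23e-07; adjusted p = 0.774 and 0.250 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 18 and 13 of 18 cases, with 1 higher each (adjusted p = 3.86e-03 and 5.76e-03; adjusted p = 0.357 and 0.250 with an estimated correlation). Smooth muscle genes were higher in 8 of 10 cases in urothelium (median 0.63, adjusted p = 0.0370; adjusted p = 0.250 with an estimated correlation), with Myh11 at 2.11. Immune genes were lower there in 7 of 12 cases with 1 higher (median -0.29, adjusted p = 0.0353; adjusted p = 0.382 with an estimated correlation).

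Between SMARTer and Ovation at 2 ng of FF RNA, 6368 of 12044 genes differed in BC57 cells and 6588 of 13583 in urothelium (3518 and 3342 after thinning). Both mitochondrial rRNA genes were higher with SMARTer (medians 2.37 and 2.25), mt-Rnr1 at 25771 ± 1634 against 3679 ± 443 CPM in BC57 cells, while the mitochondrial protein gene mt-Nd3 was lower (35.7 ± 0.992 against 1117 ± 62.8 CPM, -4.97). Mitochondrially encoded protein genes were lower in 12 of 13 cases in BC57 cells and 11 of 13 in urothelium (medians -1.54 and -1.46), histone genes in 40 of 55 with 6 higher and 22 of 36 with 3 higher (medians -1.04 and -1.03), and small noncoding RNA genes in 10 of 15 with 2 higher and 11 of 14 with 3 higher (medians -1.42 and -1.72). Ribosomal protein genes were higher in 43 of 82 cases with 20 lower, and 45 of 82 with 17 lower (medians 0.27 and 0.39), Rplp2 by 2.15 and 2.03. In BC57 cells camera adjusted p ran from 1.64e-07 to 0.0236 over these lists, and each had adjusted p = 0.625 with an estimated correlation. In urothelium it stayed at or under 0.0130, and no list held with an estimated correlation. There smooth muscle genes were higher in 8 of 10 cases (median 0.78, adjusted p = 0.0130; adjusted p = 0.474 with an estimated correlation), Myh11 by 1.5, and 3 of 4 erythroid genes were higher, among them Hbb-bs (4.44). Upk2 was higher with SMARTer, at 599 ± 20.7 against 333 ± 26.6 CPM (0.85).

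Shares of all counts weigh a class by its most abundant genes. Mitochondrially encoded protein genes took 7.09 ± 0.378% of counts in FFPE and 2.72 ± 0.0896% in FF BC57 cells with Ovation, and 2.02 ± 0.320% and 0.524 ± 0.0423% with SMARTer (2 ng, n = 3, exact permutation p = 0.1 for each). In urothelium they took 6.01 ± 0.157% and 5.19 ± 0.201% with Ovation. A share could move against the count of genes. Small noncoding RNA genes took 2.18 ± 0.213% in FFPE and 2.86 ± 0.257% in FF urothelium with Ovation, and Rn7sk alone 1.14 ± 0.0798% and 2.32 ± 0.211% (exact permutation p = 0.1 for each), although 15 of 18 such genes had risen. Mitochondrial rRNA genes took 7.03 ± 3.36% in FFPE and 10.6 ± 1.6% in FF urothelium with SMARTer (exact permutation p = 0.2). The 10 highest genes of a library took 28 ± 0.957% of SMARTer FF counts and 9.77 ± 0.533% of Ovation FF counts in BC57 cells, and 32.2 ± 2.22% and 15.8 ± 0.0616% in urothelium (exact permutation p = 0.1 for each). Gm23935 alone took 12.2 ± 1.08% of the SMARTer and 0.181 ± 0.0195% of the Ovation counts of FF BC57 cells.

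**Figure D4:**
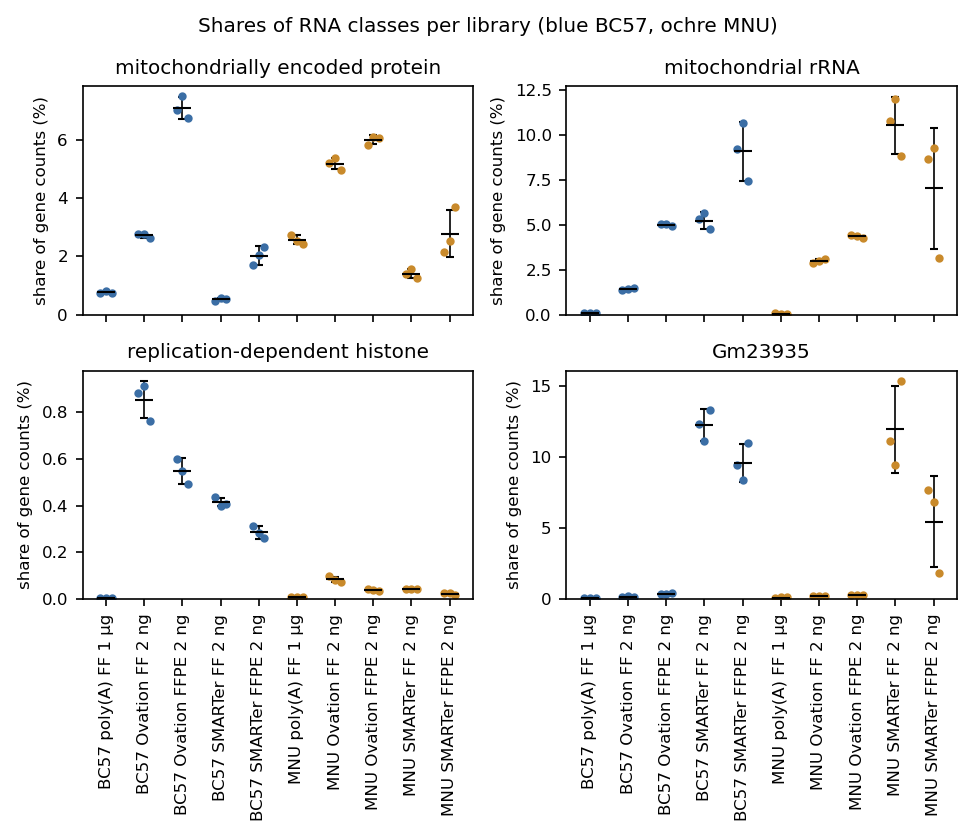
Share of library counts, in percent, taken by RNA classes at 2 ng, by sample, kit and preservation. Mitochondrially encoded protein genes took 7.09% in FFPE and 2.72% in FF BC57 cells with Ovation.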

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

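Of the tests below, those of depth, of different tissue pieces, of the spread between repeat libraries and of other splits of the samples were chosen only after the results were seen. The tests of genomic DNA, of a swap of labels, of gene length and of GC content were set before their values were seen.

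A difference between the samples in FFPE effect is taken up first. With Ovation at 2 ng, 857 of 14527 genes showed one (619 higher, 238 lower). Other splits of the 12 libraries, with FFPE and FF exchanged within each sample, gave as many genes in 5 of 100 cases, the real one included, and the highest of the others was 1161. These splits can turn the FFPE effect that both samples share into a difference. They do not show what no difference would give, and neither exclude chance nor argue for it. With SMARTer the real count was 0, all 100 splits gave as many, and the highest gave 2665. BC57 cells are a cell line and urothelium is tissue from mice, so a biological difference in response to fixation stays open and was not tested.

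In the 33 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split called most genes in 26 of them, from 1 gene to 16370 (poly(A)). Each other split mixes the groups, so real differences can widen its spread and lower its count. The 26 do not argue against chance. The highest other split gave 0 genes except for 250 pg against 2 ng in FF BC57 cells with Ovation (real 23, highest other 1) and with SMARTer (real 0, highest other 5), and in FF urothelium with SMARTer (real 0, highest other 3). In 7 comparisons of inputs the real count was 0.

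In each of the 4 groups of SMARTer FFPE libraries, the library numbered 3 held counts in more genes than the other two. Depth is argued against, because after thinning to 1 total the smallest excess was 1634 genes. A swap of the BC57 and urothelium labels is argued against as well, because each such library correlated better with the mean of the SMARTer FF libraries of its own sample at 2 ng than with that of the other sample, by a smallest difference in r of 0.190 over the 10274 genes called at 2-fold or more in poly(A). Genomic DNA in the library may be the source, as a hypothesis: 1293 olfactory and vomeronasal receptor genes took from 0.101% to 0.790% of counts in these 4 libraries, at most 0.00457% in the 8 others, and at most 0.00951% in the 12 SMARTer FF libraries. No biological explanation was tested for this pattern, since the 3 libraries of a group share an RNA sample.

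Between FFPE and FF at 2 ng with Ovation, 3916 genes differed in BC57 cells and 4975 in urothelium. Different pieces of tissue are argued against for the genes called in both samples, of which 97.7% went the same way although BC57 cells are a cell pellet. GC content is argued against as a cause common to all 4 comparisons, since Spearman's rho between fold change and GC content was -0.041 in BC57 cells with Ovation, but stays open for urothelium with Ovation (-0.111) and for BC57 cells and urothelium with SMARTer (-0.209 and -0.164). Gene length stays open as well: rho between fold change and length was positive but small in the 4 comparisons, 0.104, 0.143, 0.189 and 0.142. For the genes called in urothelium alone, different pieces of tissue and a biological change before fixation cannot be told apart from fixation, because FFPE and FF parts differ in all of these together.

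Fewer genes differed between BC57 cells and urothelium at 50 pg than at 2 ng with Ovation. On FFPE, lower depth is argued against, since 50 pg libraries held 2985318 to 4539909 counts and 2 ng ones 2605346 to 4072971. Thinned, they gave 3849 and 6709 genes, a ratio of 1.74. On FF the thinned ratio was 1.44 (4782 and 6868), which argues against depth as the whole cause. A contribution of depth stays open there. A larger spread between repeat libraries may contribute: their mean r after thinning was lower at 50 pg in all 4 pairs of groups, by at least 0.0460. No biological explanation was tested, since both inputs come from the same RNA.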

How the results depend on the processing

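Chosen only after the results were seen were the settings without the SMARTer FFPE libraries numbered 3, the left-out libraries for class shares, and the settings of the genes singled out under other observations; the other settings were fixed before the data were examined. Values below are given as counts of genes past the threshold, log2 fold changes, correlations or ratios, with the value as reported first. Unless a cause is given, the cause was not tested.

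Counts of genes stayed within 1.5 times the reported value in 33 of 35 comparisons with DESeq2's size factors in edgeR, in 25 of 35 with DESeq2, in 23 of 35 without a filter, in 26 of 35 with the replicate number as a block, in 18 of 35 after thinning and in 11 of 11 with limma on the deposited log2 values. Of the fold changes of single genes, DESeq2's size factors left 469 of 469 with the same direction and side of the threshold, limma 135 of 135, and DESeq2 443 of 468, with 5 that lost the threshold and 20 that gained it. Without a filter 462 of 469 were the same (4 lost it, 2 gained it, 1 reversed), with the block 460 of 469 (4 lost it, 4 gained it, 1 reversed) and after thinning 372 of 408 (23 lost it, 5 gained it, 8 reversed). Some of the 469 genes gave no value after thinning, since they had too few counts to be tested. With 1 library left out, 2695 of 2893 values were the same, 150 lost the threshold, 23 gained it and 25 reversed. Without both SMARTer FFPE libraries numbered 3, 13 of 15 were the same and 2 gained it.

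Thinning to 651879 counts lowered most large counts, because fewer counts were left. Between BC57 cells and urothelium 16370 became 7414 (poly(A)), 11183 became 6709 (Ovation FFPE 2 ng) and 11244 became 5985 (SMARTer FF 2 ng). Between FFPE and FF, 3916 became 1727 (BC57 Ovation), 4975 became 2368 (urothelium Ovation) and 2291 became 837 (BC57 SMARTer), and the Ovation difference of FFPE effects went from 857 to 272. Between kits in BC57 cells and urothelium, SMARTer against Ovation went from 6368 to 3518 and from 6588 to 3342, Ovation against poly(A) from 8471 to 3955 and from 9123 to 4207, and SMARTer against poly(A) from 8336 to 3126 and from 9404 to 3498. Counts between inputs with Ovation went from 3 to 16 (50 pg FF BC57), 0 to 3 (50 pg FFPE BC57), 0 to 9 (50 pg FF urothelium) and 23 to 14 (250 pg FF BC57), where the cause was not tested. Fold changes that reversed after thinning included Upk2 at 50 pg in FF urothelium with Ovation (0.13 to -0.06), Gapdh and Upk2 at 250 pg in FFPE urothelium with Ovation (0.04 to -0.0020, 0.05 to -0.06) and in FF urothelium with SMARTer (-0.03 to 0.12, 0.02 to -0.04), and the difference of FFPE effects for Upk2 with Ovation (0.73 to -0.58) and SMARTer (-0.22 to 0.13).

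Without a filter on low counts, counts went from 1244 to 2058 (BC57 against urothelium, SMARTer FFPE 250 pg), from 271 to 85 (FFPE against FF urothelium, SMARTer) and from 0 to 306 (SMARTer difference of FFPE effects). Between 50 pg and 2 ng with Ovation they went from 3 to 61 (FF BC57), 0 to 7 (FFPE BC57) and 0 to 13 (FF urothelium), and between 250 pg and 2 ng from 23 to 59 (FF BC57), 13 to 34 (FFPE BC57) and 1 to 7 (FFPE urothelium). With SMARTer they went from 0 to 5 (FF BC57), 0 to 1 (FFPE BC57) and 0 to 7 (FF urothelium). Upk2 between SMARTer and poly(A) in BC57 cells reversed from 0.05 to -0.04. The cause was not tested.

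DESeq2 gave 2549 for 1244 (BC57 against urothelium, SMARTer FFPE 250 pg), 1835 for 271 (FFPE against FF urothelium, SMARTer) and 74 for 0 (SMARTer difference of FFPE effects). Between inputs with Ovation it gave 35 for 3 (50 pg FF BC57), 171 for 0 (50 pg FFPE BC57), 23 for 0 (50 pg FF urothelium), 23 for 3 (50 pg FFPE urothelium) and 29 for 13 (250 pg FFPE BC57), and with SMARTer 7 for 0 (FFPE BC57) and 2 for 0 (FF urothelium). DESeq2's size factors in edgeR gave 7 for 3 (50 pg FF BC57) and 2 for 1 (250 pg FFPE urothelium, Ovation). Without both SMARTer FFPE libraries numbered 3, BC57 against urothelium gave 2963 for 1244 at 250 pg and 9280 for 4489 at 2 ng, and the SMARTer difference of FFPE effects 524 for 0. The cause was not tested.

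With the replicate number as a block, counts went from 271 to 76, with 70 higher and 6 lower (FFPE against FF urothelium, SMARTer), and from 0 to 1 (SMARTer difference of FFPE effects, where Upk2 reversed from -0.22 to 0.0043). At 50 pg against 2 ng with Ovation they went from 3 to 42 (FF BC57), 0 to 5 (FFPE BC57), 0 to 3 (FF urothelium) and 3 to 5 (FFPE urothelium), and at 250 pg from 23 to 80 (FF BC57), 13 to 33 (FFPE BC57) and 1 to 12 (FFPE urothelium). Residuals of libraries with the same number in different groups correlated at a mean r of 0.011 for Ovation (-0.030 to 0.14), 0.11 for SMARTer (-0.18 to 0.56) and -0.075 for poly(A) (-0.22 to 0.11). A library was closest to one of its own number in 21 of 36, 21 of 24 and 1 of 6 cases. The identifiers of the SMARTer libraries run in 3 sets of 8, which match the numbers except that BC57 FF 250 pg libraries 1 and 3 are exchanged. By these sets the mean r was 0.14 (0.0081 to 0.56), 37 of 84 pairs were not over 0.1, and 23 of 24 libraries were closest to one of their own set. Of the gene lists, 3 passed camera without the block and not with it: urothelial genes in BC57 against urothelium with SMARTer FFPE at 2 ng (adjusted p = 0.109), and fibroblast and mitochondrial rRNA genes in FFPE against FF urothelium with Ovation (adjusted p = 0.0636 and 0.0705). No label pairs the libraries, and these values do not exclude a pairing within either low-input kit.

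Leaving out 1 library changed counts as follows, lowest and highest, with fewer libraries in each test. BC57 against urothelium with SMARTer FFPE gave 161 to 2628 for 1244 (250 pg) and 1121 to 7408 for 4489 (2 ng). FFPE against FF with SMARTer gave 1164 to 2487 for 2291 (BC57) and 0 to 4124 for 271 (urothelium), and the difference of FFPE effects 0 to 168 for 0. Inputs of 50 pg against 2 ng with Ovation gave 0 to 15 for 3 (FF BC57), 0 to 2 for 0 (FF urothelium) and 0 to 2 for 3 (FFPE urothelium), and 250 pg against 2 ng gave 8 to 49 for 23 (FF BC57), 8 to 16 for 13 (FFPE BC57), 0 to 6 for 0 (FF urothelium) and 0 to 3 for 1 (FFPE urothelium). In 179 of 222 cases the count stayed within 1.5 times. In urothelium the fold changes between inputs that reversed were those of Gapdh (0.23; -0.02 to 0.38), Actb (-0.02; -0.06 to 0.02) and Upk2 (0.04; -0.12 to 0.13) for 50 pg Ovation FFPE, Actb (0.04; -0.01 to 0.09) and Upk2 (-0.02; -0.08 to 0.03) for 250 pg Ovation FF, and Actb (-0.01; -0.05 to 0.02) and Upk2 (0.05; -0.06 to 0.14) for 250 pg Ovation FFPE. With SMARTer in urothelium they were Gapdh (-0.03; -0.08 to 0.02) and Upk2 (0.02; -0.01 to 0.05) on FF, and Actb (0.25; -0.19 to 0.64) and Upk2 (-0.07; -0.51 to 0.36) on FFPE. In BC57 cells with SMARTer they were Gapdh (0.03, from -0.04 to 0.06) and Upk2 (-0.30, from -0.56 to 0.19) on FF, and Gapdh (0.06, from -0.07 to 0.12) and Actb (-0.02, from -0.10 to 0.04) on FFPE. Upk2 between SMARTer and poly(A) in BC57 cells (0.05) ran from -0.41 to 0.25, and its SMARTer difference of FFPE effects (-0.22) from -0.64 to 0.08. None of these fold changes had passed the threshold.

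Ratios of class shares kept their side of 1 in 391 of 396 cases. The 5 exceptions were the ribosomal protein ratio of SMARTer over Ovation in FF BC57 cells (1.01; 0.987 to 1.02), the Malat1 ratio of SMARTer over Ovation in FF urothelium (0.967; 0.928 to 1.00) and the Rn7sk ratio of FFPE over FF BC57 cells with Ovation (0.971; 0.923 to 1.03). The differences in genes detected reversed without the 2 ng SMARTer FFPE library numbered 3 (BC57 -228.7, from -790.3 to 419.2; urothelium -2168.3, from -3865.3 to 988.5), and in BC57 cells also without 250 pg library 1 or 2 (26.7 and 77.7). They did not reverse without both libraries numbered 3 (-142.5 and -708.5). At the depth as deposited they reversed for 50 pg FF urothelium (-244.7 to 1.3) and 250 pg FF BC57 with Ovation (-83.3 to 631.3), where libraries differ in total, and at a minimum of 10 counts for 250 pg FF BC57 with SMARTer (-49.0 to 17.3).

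Correlations of fold changes with poly(A) stayed positive in all settings. Thinning raised r from 0.927 to 0.954 and from 0.970 to 0.973 (Ovation FF at 50 pg and 2 ng), from 0.897 to 0.933, 0.926 to 0.948 and 0.952 to 0.959 (Ovation FFPE at 50 pg, 250 pg and 2 ng), and from 0.939 to 0.963 and 0.959 to 0.971 (SMARTer FF at 250 pg and 2 ng). Without a filter r fell to 0.810, 0.842 and 0.871 (Ovation FF at 50 pg, 250 pg and 2 ng; 0.951 as reported at 250 pg), 0.758, 0.801 and 0.849 (Ovation FFPE), 0.807 and 0.820 (SMARTer FF), and 0.481 and 0.550 (SMARTer FFPE; 0.780 and 0.859 as reported), where genes with few counts enter. Genes of at least 10 CPM in poly(A) gave 0.944 and 0.979 (Ovation FF at 50 pg and 2 ng), 0.920, 0.947 and 0.966 (Ovation FFPE), and 0.961 and 0.976 (SMARTer FF). Spearman's rho was 0.973 for Ovation FF and 0.974 for SMARTer FF at 2 ng, and 0.870, 0.911 and 0.944 for Ovation FFPE. The authors' log2 values gave 0.978 and 0.976 for Ovation and SMARTer FF at 2 ng, and 0.934 and 0.956 for Ovation FFPE at 250 pg and 2 ng. With 1 library left out, r ran from 0.898 to 0.914 and from 0.964 to 0.967 (Ovation FF at 50 pg and 2 ng), 0.866 to 0.871, 0.908 to 0.915 and 0.947 to 0.948 (Ovation FFPE), and 0.906 to 0.923 and 0.945 to 0.962 (SMARTer FF).

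Mean correlations between repeat libraries fell after thinning because fewer counts were left, to 0.957, 0.943 and 0.911 in FF BC57 (0.984, 0.971 and 0.927 at 2 ng, 250 pg and 50 pg with Ovation), 0.944, 0.916 and 0.872 in FFPE BC57 (0.983, 0.948 and 0.894), 0.937 and 0.859 in FF urothelium (0.975 and 0.886 at 2 ng and 50 pg) and 0.925, 0.869 and 0.808 in FFPE urothelium (0.972, 0.905 and 0.834). SMARTer FF fell to 0.956 and 0.939 in BC57 cells (0.987 and 0.962) and 0.948 and 0.919 in urothelium (0.987 and 0.95), and poly(A) to 0.961 and 0.946 (0.999 and 0.998). Spearman's rho moved to 0.984 and 0.898 (FFPE BC57 at 2 ng and 50 pg), 0.975, 0.915 and 0.845 (FFPE urothelium), 0.979 and 0.899 (FF urothelium at 2 ng and 50 pg), 0.966 and 0.943 (SMARTer FF BC57), 0.981 and 0.942 (SMARTer FF urothelium) and 0.999 (poly(A) BC57). The cause was not tested.

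Among the gene lists that passed camera, 7 of 163 held with an estimated correlation between genes, 153 of 163 with fry, 160 of 163 with the block and 34 of 38 without the SMARTer FFPE library numbered 3, and the others lost the threshold in the same direction. With an estimated correlation, the number of lists fell from 13 to 1 (poly(A)), 13 to 1 and 13 to 0 (Ovation FF and FFPE) and 15 to 1 and 15 to 0 (SMARTer FF and FFPE) for BC57 against urothelium. For FFPE against FF it fell from 9 and 16 to 0 (Ovation, BC57 and urothelium) and from 11 and 12 to 0 (SMARTer), and between kits from 5 and 8 to 0 (SMARTer against Ovation), 8 and 8 to 2 (Ovation against poly(A)) and 8 and 9 to 0 (SMARTer against poly(A)). A higher correlation widens the null spread of a list by construction. Fry gave 25 (poly(A)), 22 and 23 (Ovation FF and FFPE) and 25 (SMARTer FF) for BC57 against urothelium, 7 for FFPE against FF urothelium with SMARTer, and 14 and 16, 20 and 21, and 18 and 22 between kits in the same order. Fry tests each list against no change rather than against other genes.

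Shares of poly(A) calls recovered stayed within 1.5 times in 49 of 60 cases with 1 library left out, in 9 of 10 with DESeq2, in 9 of 10 without a filter, in 10 of 10 with the block, and in 5 of 10 when the poly(A) libraries were thinned too. The other 5 rose, from 34.7% to 58.3% and 37.5% to 59.5% (Ovation FF at 50 pg and 250 pg), 26.4% to 44.9% (Ovation FFPE at 50 pg), and 7.32% to 17% and 26.5% to 44.2% (SMARTer FFPE at 250 pg and 2 ng). Correlations of FFPE effects had the same sign throughout. They moved by less than their spread in 6 of 6 cases with DESeq2, in 4 of 6 after thinning, in 66 of 72 with 1 library left out and in 0 of 6 without a filter.

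Depth limits how many genes pass: with fewer counts left, thinning took the poly(A) count from 16370 to 7414 and that of SMARTer FF at 2 ng from 11244 to 5985. On simulated data 0% of 2-fold and 9% of 4-fold changes between BC57 cells and urothelium were found for Ovation FFPE at 50 pg, against 75% and 92% for Ovation FF at 2 ng. Depth does not account for that gap, since the former libraries held 2985318 to 4539909 counts and the latter 1843795 to 2300831. The cause was not tested, and a gene not called in that comparison is not shown to be unchanged. SMARTer FFPE and the comparisons of inputs were not simulated.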

Other observations

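All genes and chromosomes in this part were chosen only after their values were seen. At 2 ng of FF RNA and in the poly(A) libraries, the sex-linked genes of BC57 cells and urothelium differed. The X-inactivation RNA Xist stood at 114 ± 2.60 CPM in BC57 cells and 0.851 ± 0.250 CPM in urothelium with poly(A), with log2 fold changes of 7.01 (poly(A)), 6.99 (Ovation) and 5.50 (SMARTer). Xist overlaps Tsix on the other strand, and how strand was used in counting is not known here. Genes of the Y chromosome were present in both samples and lower in BC57 cells: Ddx3y stood at 20.1 ± 0.917 against 99.3 ± 10.7 CPM (-2.30, -2.51 and -2.37 in the same order), and Kdm5d (-2.47, -2.54 and -2.57), Eif2s3y (-1.79, -1.57 and -1.47) and Uty (-2.81, -3.10 and -3.35) went the same way. No test of their cause was run.

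Further single genes chosen in this way follow. Hoxb9 stood at 265 ± 5.18 CPM in BC57 cells and 2.39 ± 0.270 CPM in urothelium with poly(A) (6.81, 6.10 with Ovation and 6.88 with SMARTer), whereas Hoxa9 was lower (-6.79, -6.67 and -7.20). The tumour suppressor gene Cdkn2a stood at 179 ± 5.78 against 0.900 ± 0.0374 CPM (7.64 with poly(A) and 7.03 with SMARTer), and at a ratio of 421 (95% counting interval 75.3 to 16683) with Ovation, where urothelium had 1 count. Its neighbour Mtap was higher by 2.16, 2.29 and 2.11. Trp53 stood at 239 ± 1.21 against 61.9 ± 2.88 CPM (1.95, 1.96 and 2.16), and Myc at 225 ± 1.52 against 26.1 ± 1.47 CPM (3.10, 2.84 and 2.78).

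Medians of the log2 fold changes over the protein-coding genes of each chromosome were also compared. Chromosome 14 had the lowest, -0.65 with poly(A) over 499 genes (95% bootstrap interval -0.82 to -0.46), -0.53 with Ovation (-0.72 to -0.29) and -0.53 with SMARTer (-0.75 to -0.37). Chromosome 8 had 0.38 with poly(A) (0.26 to 0.49), 0.30 with Ovation and 0.31 with SMARTer, and chromosome 5 had 0.32, 0.25 and 0.28. Chromosomes 1 (-0.45, -0.40 and -0.44) and 4 (-0.42, -0.46 and -0.47) were lower in BC57 cells. With poly(A), chromosomes 3 (-0.31), 6 (-0.33), 7 (-0.29) and 9 (-0.34) were lower too, and chromosome 11 was higher (0.18). The median of all genes tested with poly(A) was -0.12. Chromosome 13 had 0.02 with poly(A), 0.31 with Ovation and 0.21 with SMARTer. Whether these medians follow copy number was not tested, since no DNA was measured in the values used here.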
